A study of Danio rerio with 12 samples.

How the data were processed

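Total RNA from pools of whole zebrafish larvae at 96 hpf was hybridised to 12 Affymetrix zebrafish arrays, 3 for each of 4 labelled exposures. The deposited values are MAS5 signal, an intensity per probe set on a linear scale, made by the authors in Affymetrix Expression Console per the submitters' processing notes, which give no versions. The trimmed mean of each array (2% off each side) was computed, and the largest deviation from their median was 0.00225%, under the tolerance of 5% fixed beforehand, so the values were used as deposited and taken as log2(signal + 16). Of 15617 probe sets, 115 controls were left out. Gene symbols came from a table of the array's probe sets and were brought up to date with a RefSeq gene table, matched by Entrez gene ID for 10718 probe sets, where 1 symbol changed. In all 10802 probe sets had 1 symbol, 135 had several and 4680 had none. Positions are not given, because no genome build is named for the arrays. Probe sets with a mean log2 value under the 25th percentile over the 12 arrays were left out, which left 11626. Array values carry no counts, so no depth per library is given, and dim probe sets such as 2 others for cyp19a1b limit what can be measured.

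Comparisons used limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a variance trend, on group plus the description letter as a batch term, two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all probe sets tested. The median correlation of libraries was 0.985 within a letter and 0.969 between letters. Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names the 12 largest rises and falls among probe sets with 1 symbol that passed and had the same sign in letter C and in letter B. It also names the 5 with the smallest p where fewer than 5 passed, a fixed set of AHR and estrogen genes, and members of lists that passed. The gene f13a1b, the signals of single libraries given for genes other than cyp1a and cyp19a1b, and the mpx probe sets were singled out after their values were seen. Gene lists numbered 22, with 733 genes of which 482 had a probe set. The 19 with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, with 1 probe set per gene and adjustment over lists, and with an estimated correlation and fry beside it. Lists of estrogen-responsive genes, of which 3 were measured, pituitary hormones, and yolk and oocyte genes were too small.

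Because cyp1a and cyp19a1b contradicted the titles of several libraries, more fits were reported beside the planned one, and every value says which it comes from. The fit to the 6 libraries labelled DMSO and E2+TCDD had been planned as an alternative. The grouping by description number was chosen after the values were seen. It uses labels alone: each letter B library takes the group of the letter C library with the same number, which gives 8 libraries, 2 per group, and leaves out 4. Counts without libraries whose markers oppose their title, all 6 of them in the 12-library fit and 2 of them together in the 6-library fit, were run and are not reported, because they pick libraries by a measured outcome. The comparisons of E2 and of TCDD with DMSO share the DMSO libraries, so unchanged groups were simulated against them 100 times, and 3 controls cannot be split into separate sets of 2.

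Alternatives were pseudocounts of 1 and 64, a filter at the 50th percentile and none, quantile normalisation, median centring, no batch term, 3 blocks in place of 2 letters, the replicate number as a block, array weights, no variance trend, only the groups compared, and leaving out each library. The replicate number was checked as a pairing: before the letter term every pair of libraries with 1 number correlated over 0.1, since replicate 1 always has letter C, and after it 0 of 12 pairs of replicates 2 and 3 did. On simulated data with 200 changed probe sets, limma found 56.4% of log2 changes of 0.5, 94.6% of 1 and 99.7% of 2 in the 12 libraries, 63.0%, 98.5% and 100% in the 6, and 41.5%, 93.1% and 100% in the grouping by number. The share of false calls was 5.58%, 6.53% and 5.88%. These shares hold for changes that follow the group labels, with independent noise. They do not hold for genes that respond where markers contradict the titles, since cyp1a passed in no comparison of the 12-library fit. A lack of calls in that fit is therefore no sign that nothing changed.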

Results

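Gene expression was measured in whole zebrafish larvae collected at 96 hours post fertilisation (hpf), on 12 single-colour Affymetrix arrays, each hybridised with RNA from a pool of larvae. The labels give 4 groups with 3 libraries each: the solvent DMSO, the estrogen 17beta-estradiol (E2, 0.1 µM), the dioxin TCDD (1 nM), and both compounds together (E2+TCDD). TCDD activates the aryl hydrocarbon receptor (AHR) and E2 activates estrogen receptors, and the series title asks for unique and overlapping responses to them. Each library's description carries a number and a letter, C in 4 libraries (replicate 1 of each group) and B in 8. The letter was taken as the mark of the 2 batches that the series text mentions, which is an inference. The signal, scaled by the depositors to the same trimmed mean in each array, was compared for 11626 probe sets of 7309 named genes plus unnamed probe sets. The number of arrays limits the precision, and each p-value measures the spread between these arrays, some of which is technical.

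Expression of 2 marker genes contradicted the titles in 6 of the 8 letter B libraries. The signal of cyp1a, the monooxygenase gene induced through the AHR, was 329.4 in the library labelled DMSO 2 and 413.4 in that labelled DMSO 3. It was 323.8 and 263.9 in the libraries labelled TCDD 2 and TCDD 3, but 21022.5 and 21650.5 in those labelled E2 2 and E2 3. The libraries labelled E2+TCDD 2 and E2+TCDD 3 had 20170.0 and 21509.5. The signal of cyp19a1b, the estrogen-induced brain aromatase gene, was high in the libraries labelled DMSO 3 (287.0), E2 3 (267.1), TCDD 3 (256.9) and E2+TCDD 3 (256.4). It was low in those labelled DMSO 2 (50.2), E2 2 (45.7), TCDD 2 (52.1) and E2+TCDD 2 (36.1). In the 4 letter C libraries both genes matched the titles. There cyp1a was 381.6 for DMSO 1, 414.7 for E2 1, 21109.4 for TCDD 1 and 23173.2 for E2+TCDD 1, and cyp19a1b was 46.3, 296.5, 70 and 255.9 in that order. Among all 12 libraries the lowest high value of cyp1a was 48.6 times the highest low value, and for cyp19a1b the ratio was 3.65. For this reason each group below is named as it was labelled, and no library was assigned to a group by its own values.

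**Figure D1:**
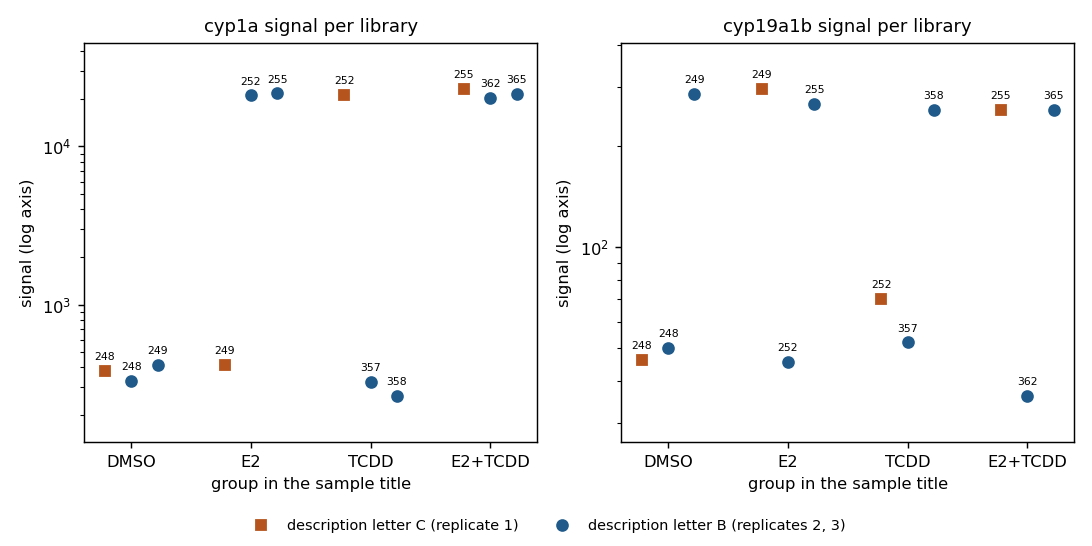
Array signal (log axis) of cyp1a and cyp19a1b in each of the 12 libraries, by labelled group; squares are letter C, circles letter B, and the description number stands beside each point. Both libraries labelled E2 with letter B lie with the high cyp1a values, and both labelled TCDD with letter B lie with the low ones.

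The comparison of the libraries labelled E2+TCDD with those labelled DMSO asked what the joint exposure changed, and it is the comparison in which cyp1a parted all libraries as the labels would have it. The signal of cyp19a1b did not part them, being 287.0 in DMSO 3 and 36.1 in E2+TCDD 2. The comparison therefore cannot show what E2 contributed. In the fit to all 12 libraries, alpi.2, an intestinal-type alkaline phosphatase gene, fell by 1.41 on the log2 scale (SE 0.19, n = 3 per group, limma adjusted p = 0.0176), and zgc:111983 fell by 1.16 (SE 0.18, limma adjusted p = 0.0231). These and f13a1b, a coagulation factor XIII subunit gene, were the named genes among the 7 probe sets that passed, 2 higher and 5 lower. The AHR-responsive genes cyp1a (5.79, SE 1.48, limma adjusted p = 0.146), cyp1c1 (4.69, SE 1.17, limma adjusted p = 0.143) and tiparp (1.2, SE 0.31, limma adjusted p = 0.146) did not pass. The spread in that fit includes the conflicting libraries of the other 2 groups. The gene cyp19a1b differed by 0.54 (SE 0.79), by 2.13 in letter C and by -0.25 in letter B, so its difference did not hold within both batches. The count of 7 was 0 without the library labelled DMSO 2, without E2+TCDD 2 or without E2+TCDD 3, 1 without DMSO 3, 14 without E2+TCDD 1, 23 without DMSO 1 and 259 in letter B alone. It was also 295 with 3 blocks, 209 with array weights, 18 (4 higher, 14 lower) after median centring and 0 without the batch term or without the variance trend.

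A fit to only the 6 libraries labelled DMSO or E2+TCDD, an alternative planned before the data were examined but made a result of its own afterwards, called 183 probe sets, 106 higher and 77 lower in those labelled E2+TCDD. Since cyp19a1b did not part these groups, the calls cannot be read as effects of E2 and TCDD together. In letter B the DMSO libraries carry the numbers 248 and 249 and the E2+TCDD libraries 362 and 365, so this fit cannot tell exposure from number series there, and the letter term does not remove the series. For the 106 rises as a set, libraries outside the fit argue against the series. With 0 as the DMSO and 1 as the E2+TCDD level, their median position was 0.0642 and -0.0397 in TCDD 2 and TCDD 3 (357 and 358). It was 0.955 and 0.848 in E2 2 and E2 3 (252 and 255). For the 77 falls the question stays open. The library labelled DMSO 1 carries the number 248 in letter C, as DMSO 2 does in letter B. These 2 libraries may therefore come from 1 RNA. The n = 3 of the DMSO group, here and in the fit to all libraries, counts arrays and may stand for 2 pools. Its spread may then hold less biological variation. The signal of cyp1a went from 374.8 ± 42.4 to 21618 ± 1505 (SD, n = 3 each), a 55.5-fold rise (log2 5.79, SE 0.08, limma adjusted p = 3.47e-11), and cyp1c1 rose 25.7-fold (log2 4.69, SE 0.09). The fit became a result of its own after cyp1a was seen to follow these labels, so the p-value of cyp1a is no separate evidence. The genes cyp3a65 (1.86), sult6b1, a sulfotransferase gene (1.74), cyb5a, a cytochrome b5 gene (1.13), and tiparp, the TCDD-inducible poly(ADP-ribose) polymerase gene (1.2), rose as well. So did the chemokine gene ccl27a (1.80), the activity-induced transcription factor genes fosab (1.44) and npas4a (1.1), nt5c2l1 (1.02) and klf2b (0.90). A probe set annotated to the myeloperoxidase gene mpx rose by 4.12. The other mpx probe set that was tested differed by -0.12 (SE 0.19), and the rest were too dim to test. All of them share their cluster number with cyp1a.

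Among the genes that fell in the 6 libraries were sox9b, a transcription factor gene of cartilage and heart development, and the keratin genes krt15 and krt94. The signal of sox9b went from 834.0 ± 49.8 to 304.7 ± 14.9 (SD, n = 3 each; log2 -1.41, SE 0.09, limma adjusted p = 8.94e-06). The log2 change was -1.50 for krt15, whose mean signal went from 2619 to 913.9, and -1.1 for krt94. Falls were also found for alpi.2 (-1.41), the bile acid binding protein gene fabp6 (-1.0), the liver fatty acid binding protein gene fabp10a (-0.85) and cyp2k18 (-1.08). The lists of intestine and hepatocyte genes as a whole did not pass (adjusted p = 0.0853 and 0.895), and the apolipoprotein gene apoeb of the hepatocyte list rose by 0.34. The rest of the 12 largest falls were zgc:111983 (-1.16), spon2b (-0.97), plekhf1 (-0.90), the chemokine gene cxcl12b (-0.86) and the lysyl oxidase gene loxa (-0.83). Some of these genes were also low in the libraries labelled TCDD 2 and TCDD 3, numbered 357 and 358, where cyp1a was low. There alpi.2 had signals of 335.0 and 261.8, cyp2k18 142.6 and 61.6, zgc:111983 664.7 and 966.4, fabp6 1443 and 878.8, and plekhf1 235.0 and 283.0. In letter C plekhf1 was 493.3 for DMSO 1 and 391.0 for E2+TCDD 1. For fabp10a the signal was 2969.6 in TCDD 2 but 1155.4 in TCDD 3. In letter C it was 4586.3 for DMSO 1, 2561.4 for E2 1, 2544.1 for TCDD 1 and 2371.6 for E2+TCDD 1, so it was low there without high cyp1a too. By contrast sox9b was 862.7 and 829.6 and krt15 2670 and 2348 in TCDD 2 and TCDD 3. Over the 77 lower probe sets the median position of these 2 libraries was 0.455 and 0.470, where 0 is the DMSO and 1 the E2+TCDD level. Over the 106 higher ones it was 0.0642 and -0.0397. The brain aromatase gene cyp19a1b differed by 0.54 (SE 0.69, limma adjusted p = 0.789), since it was high in the library labelled DMSO 3 and low in that labelled E2+TCDD 2. The count of 183 was 58 without the library labelled DMSO 2, 93 without DMSO 3, 92 without E2+TCDD 2, 100 without E2+TCDD 3, and 110 with the replicate number as a block. It was 308 with array weights, 46 without the variance trend and 23 without the batch term.

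**Figure D2:**
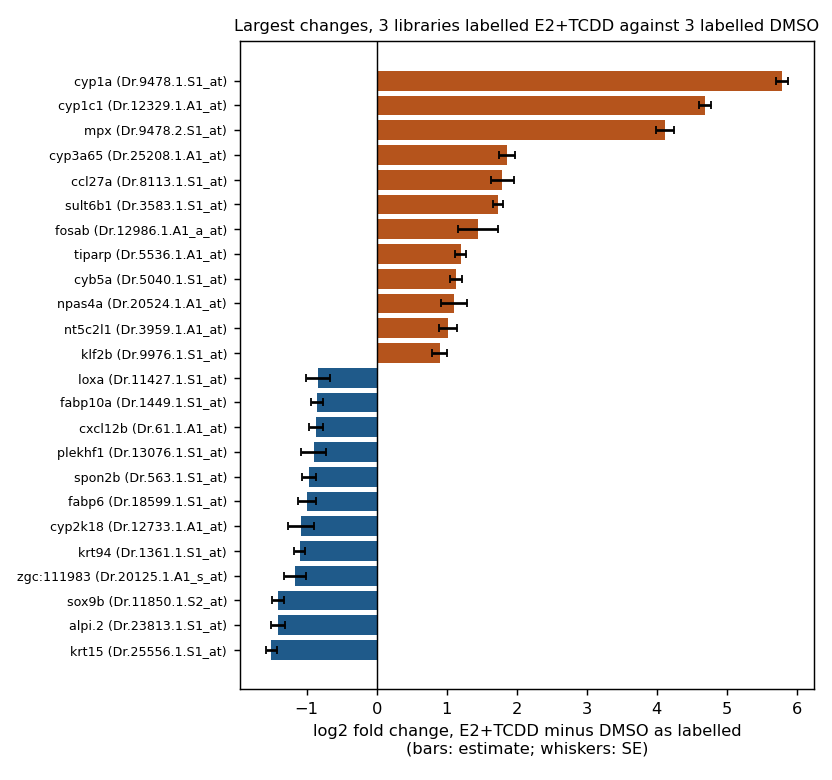
Log2 fold change of signal, E2+TCDD against DMSO as labelled, in the fit to 6 libraries (3 per group): the 12 largest rises and 12 largest falls among named genes that passed, with bars of 1 standard error. The changes run from 5.79 for cyp1a to -1.50 for krt15.

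Of 19 gene lists fixed before the data were examined and large enough to test, 10 passed in the 6 libraries with the preset correlation of camera, and none with an estimated one. Without the mpx probe set, a setting chosen after the values were seen, 8 passed with the preset correlation. Of 9 measured genes of the AHR list, 7 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 9.71e-17, and adjusted p = 0.0548 with an estimated correlation). This list holds cyp1a, whose signals were seen before the fit was made a result of its own, so its p-values are not separate evidence either. Of 16 exocrine pancreas genes, 2 fell, amy2a (-0.80) and cpa5 (-0.35), and adjusted over the list alone 11 fell and 1 rose (adjusted p = 2.22e-08, and adjusted p = 0.249 with an estimated correlation). The mean log2 signal of this list was 9.86 and 10.03 in the libraries labelled E2+TCDD 2 and E2+TCDD 3, but also 9.95 and 9.46 in TCDD 2 and TCDD 3, where cyp1a was low. Of 17 cartilage and bone genes, 6 fell, among them sox9b, hapln1a (-0.82), matn1 (-0.57) and the collagen gene col9a2 (-0.36), or 8 with 1 rise adjusted over the list alone (adjusted p = 1.48e-04, and adjusted p = 0.127 with an estimated correlation). Of 19 genes of hatching gland and skin, 2 fell, or 7 adjusted over the list alone (adjusted p = 5.90e-05, and adjusted p = 0.127 with an estimated correlation).

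In the same 6 libraries the NRF2 list of oxidative stress genes had 7 rises and 1 fall among 25 genes, including gstp1.2 (0.49), prdx1 (0.40), nqo1 (0.35) and gpx4a (-0.32), or 7 and 3 adjusted over the list alone (adjusted p = 9.88e-04, and adjusted p = 0.127 with an estimated correlation). Of 26 genes of glucocorticoid and stress response, 3 rose, the heat shock genes hsp90aa1.2 (0.79) and hsp70.3 (0.63) and fosab, or 10 with 1 fall adjusted over the list alone (adjusted p = 1.22e-05, and adjusted p = 0.249 with an estimated correlation). The clock list passed upward with 1 rise among 17 genes, bhlhe40 (0.32), or 4 adjusted over the list alone (adjusted p = 5.90e-05, and adjusted p = 0.127 with an estimated correlation). The phototransduction list passed downward with opn1mw2 (0.61) and rx1 (0.76) higher and rbp4l (-0.48) and rcvrn2 (-0.34) lower among 23 genes, or 2 higher and 6 lower adjusted over the list alone (adjusted p = 0.0313, and adjusted p = 0.249 with an estimated correlation). Of 16 leukocyte genes the mpx probe set rose and the lysozyme gene lyz fell by 0.53, or 3 rose and 2 fell adjusted over the list alone (adjusted p = 0.0409, adjusted p = 0.249 with an estimated correlation, and adjusted p = 0.327 without the mpx probe set). The list of endoplasmic reticulum (ER) chaperones passed upward with 0 of 33 genes past the limma test, over all probe sets or adjusted over the list alone (adjusted p = 0.0463, and adjusted p = 0.327 with an estimated correlation). The lists of fast muscle (adjusted p = 0.0558), DNA replication (0.0700), intestine (0.0853), neurons (0.0854), cholesterol synthesis (0.108), heart (0.144), lens (0.280), erythroid cells (0.496) and hepatocytes (0.895) did not pass.

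In the fit to all 12 libraries the same comparison had 11 lists past the test. Lower were exocrine pancreas (adjusted p = 1.39e-06), cartilage and bone (9.60e-04), hatching gland and skin (0.00118), phototransduction (0.0443) and DNA replication (0.0477). Higher were the AHR list (5.71e-05), glucocorticoid and stress (1.17e-04), clock (7.91e-04), NRF2 (0.0226), ER chaperones (0.0443) and fast muscle (0.0443). With an estimated correlation none passed, the lowest being adjusted p = 0.132. No member passed over all probe sets, with 1348 probe sets at an unadjusted p under 0.05 in limma, while adjusted over the list alone 7 AHR genes rose and 1 fell, 5 stress genes rose, and 8 pancreas, 7 cartilage and bone and 6 skin genes fell. The other counts adjusted over the list alone were 3 higher and 2 lower for NRF2, 2 and 1 for phototransduction, and 0 for clock, ER chaperones, fast muscle and DNA replication.

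The comparison of the libraries labelled TCDD with those labelled DMSO asked what TCDD changed, and cyp1a gave a different answer in each batch. Its log2 difference was 5.73 in letter C and -0.32 in letter B (1.70 in the fit, SE 1.48, limma adjusted p = 0.754), and that of cyp1c1 was 4.29 and 0.00. The smallest p-values belonged to alpi.2 (-1.29, SE 0.19, limma adjusted p = 0.0945), cnmd, the chondromodulin gene (-0.49), the pancreatic carboxypeptidase gene cpb1 (-0.58) and cyp2k18 (-1.25), none of which passed. By limma 0 probe sets passed, with 1114 at an unadjusted p under 0.05. Lists of exocrine pancreas (adjusted p = 4.17e-14), intestine (2.27e-07) and cartilage and bone (0.00402) passed downward, and fast muscle (6.67e-04) and clock (0.0279) upward, none with an estimated correlation (lowest adjusted p = 0.213). Adjusted over the list alone, 12 of 16 pancreas genes and 5 of 11 intestine genes fell. The mean log2 signal of the intestine genes was higher in the library labelled TCDD 1 (10.04) than in DMSO 1 (9.96), so its fall did not hold in letter C. It was 9.45 and 8.93 in TCDD 2 and TCDD 3, where cyp1a was low, against 9.80 and 10.10 in DMSO 2 and DMSO 3. The gene count was 126 in letter B alone, 3 without DMSO 1, 5 without TCDD 2, 26 with array weights or with 3 blocks and 1 in a fit to only the groups compared. In letter B the TCDD libraries carry the numbers 357 and 358 and the DMSO libraries 248 and 249, with low cyp1a in all of them. There the labelled exposure and the number series cannot be told apart.

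A grouping by the description number was added after the values had been seen, those of cyp1a and cyp19a1b among them. Both genes follow the numbers in its 8 libraries, so their p-values in any comparison by number are no separate evidence. Each letter B library with the number of a letter C library took the group of that library, which leaves 8 libraries with 2 per group and omits the 4 with other numbers. Libraries that share a number may come from 1 RNA, so the spread within these groups may hold no biological variation. In that grouping 149 probe sets rose and 44 fell with TCDD, 193 in all. The gene cyp1a went from a signal of 355.5 ± 36.9 to 21066 ± 61.4 (SD, n = 2 each; log2 5.83, SE 0.09, limma adjusted p = 1.91e-15), cyp1c1 rose by 4.65, tiparp by 0.98 and the receptor gene ahr2 by 0.81. The metabolic genes cyp3a65 (1.97), sult6b1 (1.83) and cyb5a (1.17) rose, as did the glucocorticoid-induced gene fkbp5 (1.24), fosab (1.22), ccl27a (1.82), esm1 (1.12) and LOC567909 (2.21). The mpx probe set rose by 4.43. Falls were found for krt15 (-1.61), sox9b (-1.57), zgc:193593 (-1.43), alpi.2 (-1.19), cxcl12b (-1.18), spon2b (-1.0), the cartilage link protein gene hapln1a (-0.95), cyp2k18 (-0.91), krt94 (-0.90), crp, the C-reactive protein gene (-0.89), pmelb (-0.79) and fzd8a (-0.78). The clock gene per2 rose by 2.4, from signals of 202.1 and 168.1 to 1116 and 978.1, yet in the libraries labelled E2+TCDD 2 and E2+TCDD 3, which this grouping omits and where cyp1a was high, its signal was 172.8 and 195.7. The same 2 libraries had 1109 and 796.2 for fkbp5, against 799.1 and 1093 in the DMSO libraries of this grouping. They had 314.6 and 204.4 for LOC567909, against 218.0 and 223.5, and 972.6 and 1418 for zgc:193593, against 1752 and 1440. For pmelb they had 389.1 and 450.7, against 338.4 and 436.0, and for fzd8a 547.3 and 718.6, against 937.8 and 689.5. The count of 193 was 44 without the library labelled DMSO 1, 64 without DMSO 2 and 71 without TCDD 1, and 37 without the variance trend or 14 without the batch term.

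In the grouping by description number 13 lists passed for TCDD, and none with an estimated correlation. In the AHR list 6 of 9 genes rose and 1 fell, or 7 and 1 adjusted over the list alone (adjusted p = 9.68e-18, and adjusted p = 0.0502 with an estimated correlation). Of 26 genes of glucocorticoid and stress response 8 rose, or 15 adjusted over the list alone (adjusted p = 4.22e-16, and adjusted p = 0.101 with an estimated correlation). Of 17 clock genes 6 rose, or 7 adjusted over the list alone (adjusted p = 6.24e-12, and adjusted p = 0.116 with an estimated correlation). Of 17 cartilage and bone genes 2 fell, or 4 with 1 rise adjusted over the list alone (adjusted p = 3.23e-04, and adjusted p = 0.115 with an estimated correlation). The others were upward for leukocytes (6.08e-06), NRF2 (0.00356), ER chaperones (0.0132) and intestine (0.0339), and downward for skin (3.23e-04), phototransduction (0.00244), lens (0.00324), DNA replication (0.00708) and pancreas (0.0115), with an adjusted p of 0.101 or more with an estimated correlation.

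**Figure D3:**
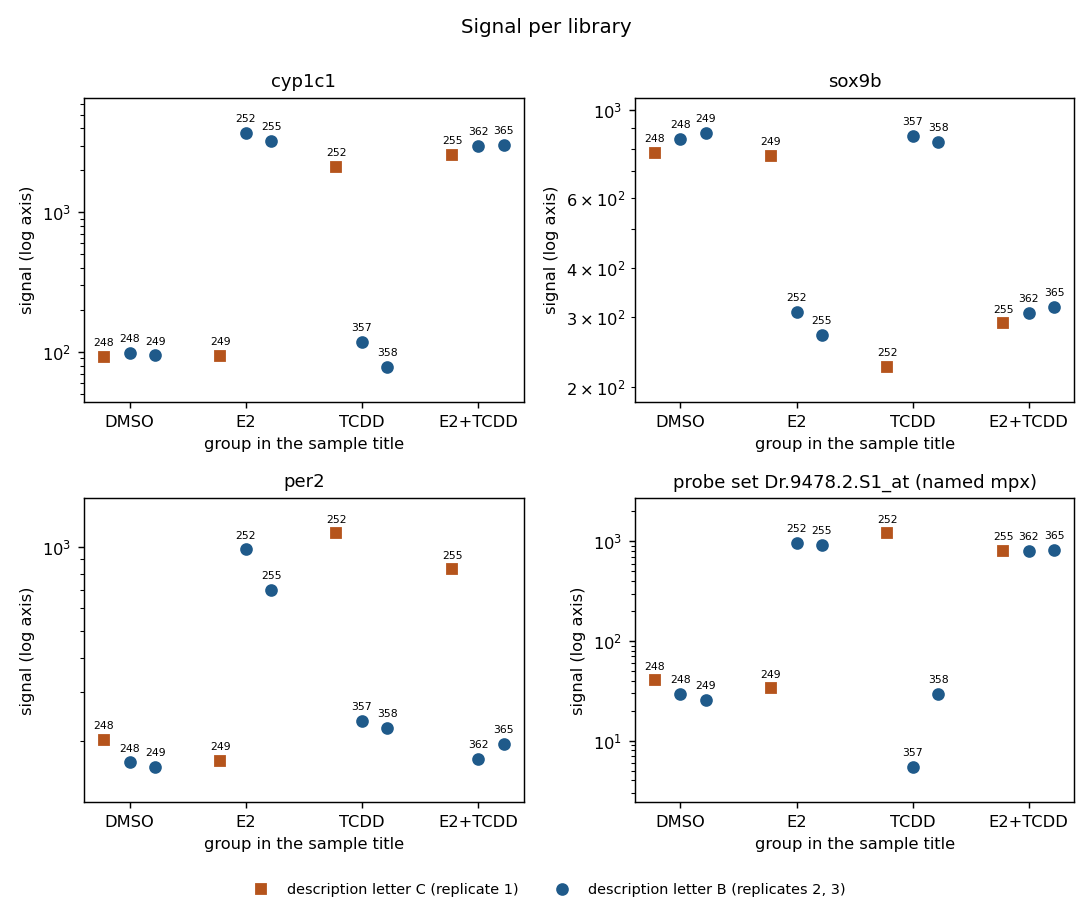
Array signal (log axis) of cyp1c1, sox9b, per2 and the probe set annotated to mpx in each of the 12 libraries, by labelled group; squares are letter C, circles letter B, and description numbers stand beside the points. The gene per2 is highest in the libraries numbered 252 and 255, with signals from 700.4 to 1116, and at most 236.7 in the others.

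The comparison of the libraries labelled E2 with those labelled DMSO asked what E2 changed. The estrogen-induced gene cyp19a1b differed by 2.33 on the log2 scale in letter C and by -0.10 in letter B (0.71 in the fit, SE 0.79, limma adjusted p = 0.888), while cyp1a differed by 0.12 in letter C and by 5.79 in letter B (3.90 in the fit, SE 1.48, limma adjusted p = 0.730). The smallest p-values belonged to alpi.2 (-0.83), angel2 (0.56) and epd (-0.47), with limma adjusted p = 0.730 for each. By limma 0 probe sets passed, with 770 at an unadjusted p under 0.05. Lists of clock (adjusted p = 4.36e-08), glucocorticoid and stress response (6.63e-08) and the AHR (5.11e-04) passed upward, and skin (1.10e-04), lens (6.37e-04), cartilage and bone (0.00716) and DNA replication (0.00716) downward, none with an estimated correlation (lowest adjusted p = 0.105). Adjusted over the list alone, 4 AHR genes rose and 1 fell. The gene count was 30 without the library labelled E2 1, 111 in letter B alone and 8 in a fit to only the 6 libraries compared.

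In the grouping by description number, with 2 libraries per group and chosen after the values were seen, 2 probe sets rose with E2. For cyp19a1b, 1 of them, the p-value is no separate evidence, since its signals were seen before that choice. The signal of cyp19a1b went from 48.2 ± 2.76 to 291.8 ± 6.72 (SD, n = 2 each; log2 2.26, SE 0.20, limma adjusted p = 1.52e-04), and that of ctrb.2, a chymotrypsinogen gene of the exocrine pancreas, from 608.4 ± 30.5 to 1186 ± 104 (log2 0.94, SE 0.13, limma adjusted p = 0.0161). In the 4 libraries this grouping omits, ctrb.2 went with cyp19a1b in 1 pair and against it in the other. It was 266.3 in that labelled TCDD 3, with high cyp19a1b, and 409.2 in TCDD 2, with low cyp19a1b, but 561.9 in E2+TCDD 3, with high, and 390.5 in E2+TCDD 2, with low cyp19a1b. The early response genes npas4a (0.86) and fosab (0.77) and the liver gene fabp10a (-0.55) did not pass, nor did cyp1a (0.21, SE 0.09, limma adjusted p = 0.999). The exocrine pancreas list passed upward, with 0 of 16 genes past the limma test over all probe sets and 9 higher adjusted over the list alone (adjusted p = 2.66e-13, and adjusted p = 0.250 with an estimated correlation). Its mean log2 signal in the same omitted libraries was 9.46 in TCDD 3, the lowest of the 12, and 9.95 in TCDD 2, but 10.03 in E2+TCDD 3 and 9.86 in E2+TCDD 2. Also upward were glucocorticoid and stress response (5.68e-11), intestine (0.00116), cholesterol synthesis (0.00770), leukocytes (0.0316) and clock (0.0372), and downward lens (0.00214) and DNA replication (0.0151), with an adjusted p of 0.250 or more with an estimated correlation. The gene count was 0 without the library labelled DMSO 1 and 1 without DMSO 2 or DMSO 3, 20 in a fit to only the groups compared, 5 with no filter on dim probe sets, 1 with the stricter filter or without the variance trend and 0 without the batch term.

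The comparison of the libraries labelled E2+TCDD with those labelled TCDD asked what E2 added in the presence of TCDD. The gene cyp19a1b differed by 1.66 in letter C and by -0.19 in letter B (0.42 in the fit, SE 0.79), and cyp1a by 0.13 and 6.08 (4.1 in the fit, SE 1.48, limma adjusted p = 0.646). By limma 0 probe sets passed, with 827 at an unadjusted p under 0.05, against 100 without the library labelled TCDD 1, 132 in letter B alone and 1 with array weights. Lists of NRF2 (adjusted p = 9.91e-07), AHR (4.23e-06), glucocorticoid and stress (1.19e-05), intestine (1.66e-04), pancreas (0.00407), leukocytes (0.00551) and ER chaperones (0.00551) passed upward, and DNA replication (0.00890) and skin (0.0165) downward, none with an estimated correlation (lowest adjusted p = 0.285). The signals of cyp19a1b had been seen when the grouping by description number was chosen. In that grouping it was the 1 probe set that passed, with a rise of 1.93 (SE 0.20, limma adjusted p = 0.00124), and no list passed. That count was 10 without the library labelled E2 2, and 0 without E2 3, without the batch term or with the stricter filter, and 2 in a fit to only the groups compared.

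The comparison of the libraries labelled E2+TCDD with those labelled E2 asked what TCDD added in the presence of E2. The gene cyp1a differed by 5.75 in letter C and by -0.03 in letter B (1.89 in the fit, SE 1.48, limma adjusted p = 0.979), and zgc:111983 had the smallest p of the named genes (-1.21, SE 0.18, limma adjusted p = 0.0898). By limma 0 probe sets passed, with 567 at an unadjusted p under 0.05, against 1 without the library labelled E2 1, 23 in letter B alone, 5 with array weights and 2 in a fit to only the groups compared. In letter B the E2+TCDD libraries carry the numbers 362 and 365 and the E2 libraries 252 and 255, with high cyp1a in all of them. There too the labelled exposure and the number series cannot be told apart. Lists of pancreas (adjusted p = 1.12e-06) and intestine (0.0168) passed downward, and fast muscle (2.25e-06) and lens (0.0309) upward, none with an estimated correlation (lowest adjusted p = 0.629). By description number 50 probe sets rose and 31 fell, among them cyp1a (5.70), cyp1c1 (4.72), ccl27a (2.46), per2 (2.1), tiparp (1.39), krt15 (-1.50), sox9b (-1.50), alpi.2 (-1.21) and the pancreatic enzyme genes ctrb.2 (-1.25, SE 0.13) and amy2a (-1.23, SE 0.14). Of 16 pancreas genes 4 fell, or 14 adjusted over the list alone (adjusted p = 6.36e-19, and adjusted p = 0.101 with an estimated correlation). Among the omitted libraries with high cyp19a1b, the mean log2 signal of this list went the other way. It was 10.03 in E2+TCDD 3, with high cyp1a, and 9.46 in TCDD 3, with low cyp1a. In the omitted libraries with low cyp19a1b it was 9.86 in E2+TCDD 2 and 9.95 in TCDD 2. Of 9 AHR genes 5 rose, or 5 with 1 fall adjusted over the list alone (adjusted p = 4.93e-21, and adjusted p = 0.0389 with an estimated correlation). The count of 81 was 25 without the library labelled E2 1 and 27 without E2+TCDD 1, and it was 21 without the variance trend, 15 without the batch term, 122 with array weights and 149 in a fit to only the groups compared.

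Against DMSO, the E2+TCDD group by description number had 99 probe sets higher and 37 lower. The gene cyp19a1b rose by 2.11 (SE 0.20, n = 2 per group, limma adjusted p = 2.23e-05), beside cyp1a (5.92), cyp1c1 (4.70) and tiparp (1.28), and sox9b (-1.49) and krt15 (-1.57) fell. The AHR list passed with 5 of 9 genes higher, or 7 with 1 lower adjusted over the list alone (adjusted p = 7.72e-21, and adjusted p = 0.0395 with an estimated correlation), 1 of 13 lists that passed. The count of 136 was 42 without the library labelled DMSO 1, 48 without DMSO 2, 32 without E2+TCDD 1 and 69 without E2 3. It was 33 without the variance trend, 17 without the batch term and 261 in a fit to only the groups compared.

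The interaction, whether the joint change departs from the sum of the single ones on the log2 scale, had 0 probe sets past limma's threshold in the 12 libraries, with 509 at an unadjusted p under 0.05 and a smallest adjusted p of 0.976, against 1 in letter B alone or with no filter on dim probe sets. Its estimate was 0.20 (SE 2.1) for cyp1a and -0.29 (SE 1.12) for cyp19a1b. By description number it was again 0 by limma, with 596 at an unadjusted p under 0.05. The pancreatic gene ctrb.2 (-1.23, SE 0.18, limma adjusted p = 0.0823), irg1l (-1.30, SE 0.21, limma adjusted p = 0.0885) and gda (-1.35) had the smallest p-values. That count was 4 without the library labelled E2 2, 1 without E2 1 and 2 with a pseudocount of 64.

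The overlap of the E2 and TCDD responses, which the title of the series asks about, was 0 shared probe sets in the 12 libraries, since neither comparison had a call, with 770 and 1114 at an unadjusted p under 0.05 in limma. It was 11 in letter B alone and 1 without the library labelled E2 1. Over all probe sets tested the log2 fold changes correlated at r = 0.52 (Spearman rho 0.50), where simulated groups without change that share the DMSO libraries gave 0.50 (from 0.449 to 0.530), and their covariance was 0.0174 against 0.0104. Probe sets are not independent replicates, while the simulations drew noise for each on its own, so their ranges may be too narrow. By description number E2 and TCDD again shared 0 probe sets (r = 0.44, simulated 0.50, from 0.482 to 0.520). E2 had only 2 calls there, so that 0 decides nothing about the overlap. TCDD and E2+TCDD shared 107, 85 higher and 22 lower, among them cyp1a, cyp1c1, tiparp, sox9b and krt15. Independent calls would give 1.27 and 0.14, a figure that leaves out the DMSO libraries shared by both comparisons. The covariance of those changes was 0.0442 against 0.0143 in the simulations (r = 0.72). The E2 and E2+TCDD calls shared 1 probe set, that of cyp19a1b.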

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

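The tests of labels, clock genes and the mpx probe set were chosen after the results were seen. The counts over other splits of the libraries were chosen before the values were examined, except those of the 6-library fit as a result of its own.

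Gene lists whose response to E2 differed with TCDD, by the interaction test with camera's preset correlation, drew attention. By description number the exocrine pancreas list had a lower joint response than the sum of the single ones (adjusted p = 7.40e-09, members at a median log2 of -0.36). Lower joint responses were also found for glucocorticoid and stress response (8.39e-08), clock (0.00160), leukocytes (0.00923), intestine (0.0263) and cholesterol synthesis (0.0373). Higher ones were found for lens, phototransduction and hepatocytes (0.0263 each). With an estimated correlation the lowest adjusted p was 0.285. By title the list of exocrine pancreas (0.00186), intestine (0.0121), lens (0.00260) and NRF2 (0.0308) had a higher joint response and clock (0.00186) a lower one, with an adjusted p of 0.653 for each with an estimated correlation. For pancreas and intestine the signs by title and by number are opposite. Of 100 groupings of the 12 libraries, the real one included, 48 gave 5 or more such lists (highest other 13), so chance is not excluded for the lists of the interaction by title. For its genes the real count of 0 is reached by all 100 groupings (highest other 11), so that count decides nothing.

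The first pattern is that cyp1a and cyp19a1b oppose the title in 6 of 8 letter B libraries. Array scaling is argued against, since after quantile normalisation cyp1a stayed on the wrong side in 4 libraries, and TCDD carried over or not taken up is argued against for cyp19a1b alone, which opposes the title in 2 libraries whose cyp1a matches it (DMSO 3 and E2+TCDD 2). Mislabelled titles may account for both genes. All 4 libraries with opposing cyp1a also correlated better, over genes outside the AHR and estrogen lists, with the side given by their cyp1a. An error in TCDD exposure would give that as well and cannot be told apart for cyp1a taken alone. This holds above all in the 2 libraries whose cyp19a1b matches the title (E2 3 and TCDD 2). Letter B holds 2 number series, 248, 249, 252, 255 and 357, 358, 362, 365. In rising order each had both genes low, cyp19a1b alone high, cyp1a alone high and both high. Letter C had the same order, from DMSO to E2, TCDD and E2+TCDD. An error in TCDD exposure alone would not put cyp19a1b in that order. Errors in both exposures would have to recreate the order of letter C in both series of letter B. These values cannot tell such errors apart from wrong titles. Over the same genes, the matching of letter C to letter B by number ranked 3 of 24 (summed r 0.604, highest other 0.715). The best matching exchanged only the libraries labelled E2 2 and E2 3, both with high cyp1a, which the omitted gene cyp19a1b parts. So this ranking cannot decide whether the description number names the pool. For the 4 shared numbers cyp1a and cyp19a1b matched across the letters, and per2 was high in 252 and 255 alone. Numbers that follow the exposure would give the match of cyp1a and cyp19a1b as well. The best matching of letter C to the 4 libraries with other numbers reached 0.655. Biological readings, such as an E2 effect on cyp1a in batch B alone, were not tested apart from these values. The values argue against such an effect as the only cause. It would not give low cyp1a in TCDD 2 and TCDD 3 (323.8 and 263.9). Nor would it give high cyp19a1b in DMSO 3 and TCDD 3 (287.0 and 256.9).

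The second pattern is that clock genes, per2 above all, were high in the libraries that share a description number with TCDD 1 and E2+TCDD 1, and it is not particular to the clock, since fkbp5 and LOC567909 were high there too. In the libraries labelled E2+TCDD 2 and E2+TCDD 3, where cyp1a is high, the 6 clock genes called by number stood at a median of 0.345 and 0.355 of the way from the DMSO to the TCDD level, with per2 at 0.00264 and 0.0713 but bhlhe40 at 0.768 and 0.537. That DMSO level comes from libraries of another number series, so an offset between series may enter the positions. Against TCDD 2 and TCDD 3 of their own series, where cyp1a was low, per2 was not higher (172.8 and 195.7 against 236.7 and 223.8). Nor was nfil3-5 (897.5 and 1014.4 against 987.1 and 1203.6), whereas cry1a, cry2, tefa and bhlhe40 were higher. AHR activation alone cannot be told apart from other causes for these genes as a set, because their positions are spread from 0.00264 to 0.768 and they were chosen by their rise at the TCDD level. The lowest per2 signal in these libraries was 2.96 times the highest in the others, which restates the pattern and favours no cause. A difference in light or hour of collection between pools could give it. The labels give no hour, so this cannot be told apart from an effect of the exposure. A response of the clock to TCDD that varies between exposures stays open, untested.

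The third pattern is the probe set annotated to mpx, a neutrophil gene, which followed cyp1a. More neutrophils are argued against, because the other 15 leukocyte genes had a median log2 change of 0.116 in the 6 libraries (quartiles -0.0405 and 0.218). The probe set could read cyp1a RNA, as it was high in 6 of the 6 libraries with high cyp1a. Its cluster number, which it shares with cyp1a, is no support, because the other mpx probe sets carry it too and did not follow cyp1a (for 1 of them 96.9 and 119.7 in the libraries labelled E2 2 and E2 3, against 174.1 and 198.3 in DMSO 2 and DMSO 3). This cannot be told apart from induction of another transcript without the probe sequences.

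Regrouping the 6 libraries of each pair of groups makes 10 splits, too few for a share under 0.05. For genes, the real count and the highest other were 0 and 3 for E2 against DMSO, 0 and 1 for TCDD against DMSO, 7 and 0 for E2+TCDD against DMSO, 0 and 1 for E2+TCDD against TCDD, and 0 and 0 for E2+TCDD against E2. For lists they were 7 and 13, 5 and 11, 11 and 7, 9 and 12, and 4 and 7 in the same order. As many were found in 10, 10, 1, 10 and 10 splits for genes and in 3, 7, 1, 4 and 4 for lists, the real one included. In the 6-library fit the real split called 183 genes (highest other 1) and 10 lists (highest other 9), each reached by 1 split.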

How the results depend on the processing

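Settings with 3 blocks, array weights, no variance trend, quantile normalisation, median centring, pseudocounts, filters, fry, only the groups compared, the replicate number as a block and leaving out libraries were chosen beforehand; the grouping by description number, the fits to it and the 6-library fit as a result of its own were chosen after the values were seen. Values of named genes never reversed. In the 12 libraries values kept direction and side of the threshold in 545 checks, lost a call in 13 and gained it in 44. In 57 checks the direction changed with no call in either setting. By number the counts in the same order were 1016, 103, 1 and 9, and in the 6 libraries 407, 50, 1 and 3. Calls of lists held in 764 checks and were lost in 109 (703 and 93 by number, 166 and 25 in the 6), and 14 by title reversed. The cause was not tested for any change below, except that a fit with fewer libraries has fewer arrays and a stricter filter fewer probe sets.

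In the 12 libraries, 3 blocks gave 26 genes for TCDD, 295 for E2+TCDD against DMSO and 9 lists for E2+TCDD against E2, where intestine (adjusted p = 0.0191) and lens (0.570) reversed. Array weights gave 26 genes for TCDD, 209 for E2+TCDD against DMSO, 1 against TCDD and 5 against E2. For E2+TCDD against DMSO there were 0 genes without the variance trend, 0 without the batch term and 18 genes with 7 lists after median centring. Without the batch term 2 lists were left for E2+TCDD against E2. With no dim filter there were 3 lists for TCDD, 7 for E2+TCDD against DMSO and 1 gene for the interaction, and with the filter at the median 3 lists for the interaction. An estimated correlation left 0 lists in all 6 comparisons, and fry called 2 for E2+TCDD against DMSO and 0 in the other 5. Only the groups compared gave 8 genes and 11 lists for E2, 1 gene for TCDD, 183 for E2+TCDD against DMSO and 2 against E2.

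Grouped by description number, genes were 2 for E2, 193 for TCDD, 136 for E2+TCDD against DMSO, 1 against TCDD and 81 against E2, and lists 13 for TCDD, 0 for E2+TCDD against TCDD, 8 against E2 and 9 for the interaction. Lists that reversed were intestine (adjusted p = 0.0339) and fast muscle (0.969) for TCDD, fast muscle (0.256) for E2+TCDD against DMSO, lens (0.809) against E2, and against TCDD pancreas (0.400), intestine (0.876), leukocytes (0.290), DNA replication (0.873), glucocorticoid and stress (0.452) and skin (0.873). In the interaction pancreas (7.40e-09) and intestine (0.0263) reversed.

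Within the grouping by number, an estimated correlation left 0 lists for E2, TCDD and the interaction, and 1 each for E2+TCDD against DMSO and against E2. No variance trend gave 1 gene for E2, 37 for TCDD, 33 for E2+TCDD against DMSO and 21 against E2. No batch term gave 0, 14, 17 and 15 in that order, 0 against TCDD, and 5 lists for the interaction. Only the groups compared gave 20 for E2, 261 for E2+TCDD against DMSO, 2 against TCDD and 149 against E2, and array weights 122 against E2. The filter at the median gave 1 gene for E2, 0 genes and 1 list for E2+TCDD against TCDD, and no dim filter 5 genes for E2 and 1 list for E2+TCDD against TCDD. By fry there were 0 lists for E2, 7 for TCDD, 8 for E2+TCDD against DMSO and 1 for the interaction. A pseudocount of 64 gave 2 genes and quantile normalisation 5 lists for the interaction. In the 6 libraries there were 308 genes with array weights, 46 without the variance trend, 23 without the batch term, 110 with the replicate number as a block, 0 lists with an estimated correlation and 5 by fry. The pairing by replicate number is not borne out beyond the letter (after the letter term r ran from -0.23 to 0.02 over 12 pairs), and as a block it moved no count in the 12 libraries by over 1.5 times.

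Leaving out libraries in turn, where a group left with 1 library is assumed to vary like the others, gave these ranges in the 12 libraries, the highest gene counts always without replicate 1. Genes ran from 0 to 111 for E2, 0 to 126 for TCDD, 0 to 259 for E2+TCDD against DMSO, 0 to 132 against TCDD, 0 to 23 against E2 and 0 to 1 for the interaction. Lists ran from 7 to 16, 4 to 9, 7 to 11, 5 to 12, 2 to 7 and 2 to 8, and the overlap from 0 to 11. By number, genes ran from 0 to 3, 44 to 158, 32 to 69, 0 to 10, 25 to 59 and 0 to 4, lists from 4 to 8, 9 to 11, 11 to 12, 0 to 3, 4 to 8 and 3 to 9, and the overlap from 0 to 1. In the 6 libraries genes ran from 58 to 182 and lists from 7 to 11. Low signal over background limits dim probe sets.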

Other observations

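All values here were picked out after they were seen. Exocrine pancreas and intestine genes were lowest in the library labelled TCDD 3, with a mean log2 signal of 9.46 over 16 pancreas genes and 8.93 over 11 intestine genes. The highest pancreas means were 10.67 in the library labelled E2 1 and 10.50 in that labelled DMSO 3, both with high cyp19a1b and low cyp1a. The library labelled TCDD 3 has high cyp19a1b and low cyp1a as well. Its signal of the elastase gene ela2 was 1525, against 6746 in the library labelled E2 1 and 5200 in that labelled DMSO 3. The estrogen list had 3 measured genes, cyp19a1b, igfbp1a and apodb, too few for the test. Their mean log2 signal, which holds cyp19a1b and is therefore no separate evidence, ran from 8.4 in the library labelled DMSO 1 to 9.27 in those labelled E2+TCDD 1 and E2 3. Of the pituitary hormone list 4 genes were measured and of the yolk and oocyte list 1, with means between 7.30 and 7.66 and between 8.84 and 9.32.

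The 4 letter B libraries with description numbers that no letter C library shares were placed between the levels of the fits that leave them out. On a scale where 0 is DMSO and 1 is TCDD by number, the 149 higher probe sets had a median position of 0.0248 in the library labelled TCDD 2 and -0.233 in TCDD 3, and 0.822 and 0.633 in E2+TCDD 2 and E2+TCDD 3. The 44 lower probe sets stood at 0.264, 0.181, 0.808 and 0.882 in the same order. On the scale of the 6-library fit, the 106 higher probe sets stood at 0.139 in the library labelled E2 1, 0.884 in TCDD 1, 0.955 in E2 2, 0.848 in E2 3, 0.0642 in TCDD 2 and -0.0397 in TCDD 3. The 77 lower probe sets stood at 0.238, 0.857, 0.709, 0.660, 0.455 and 0.470 in the same order, so the libraries labelled TCDD 2 and TCDD 3, with low cyp1a, lay near the middle for the falls. Between single libraries of letter C, without a test, 21 probe sets were at least 2-fold higher and 5 lower for E2 1 than for DMSO 1, 64 and 55 for TCDD 1, and 39 and 30 for E2+TCDD 1.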
